A study of Rattus norvegicus with 12 samples.

How the data were processed

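Gene expression was measured in N27 cells, an immortalised rat dopaminergic neural line, on 1-colour Agilent 60-mer arrays. The series' design text describes cultures grown to 80% confluence, of which 7 carried a CRISPR knockout of Vdac1, the gene for voltage-dependent anion channel 1 of the outer mitochondrial membrane, and 5 were wild type. Whether the knockout cultures came from 1 clone or several, and where in the gene the edit lies, is not given in the sources used here. Groups and sample numbers were taken from the sample labels. The p-values measure the spread between these cultures, and whether they were grown independently is not given in the sources used here.

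Per the labels' protocols, total RNA was extracted with Trizol and labelled with Cy3. Per the submitters' processing notes the images were read with Agilent Feature Extraction 10.7, while the file headers name version 10.1.1.1. The scanner files hold spot intensity on a linear scale, per the file headers: the processed signal after the software's background treatment, the mean signal, the median local background, and, as other columns, yes-or-no flags for spots well above background, saturated or uneven. The deposited value table holds log2 values with every column alike in its sorted values, as quantile normalization leaves them, with a median of 3.06 and a lowest value of 1.5, and a Spearman correlation across probes of 0.998 with the same array's scanner signal, which settled its scale and direction.

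The 12 arrays lay on 3 slides. Slides 1 and 2 were scanned on one day and slide 3 on another, and each slide held both genotypes: 2 knockout and 2 wild-type arrays on slides 1 and 3, and 3 knockout arrays and 1 wild-type array on slide 2. The 75th percentile of the processed signal ranged from 120.1 to 691.8 between arrays, 5.76-fold, and 42.3% to 53.8% of spots were well above background. No spot was saturated. The number of arrays limits the precision.

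Each array held 58717 spots that are not controls, for 45598 distinct probes. Spots flagged as uneven or as population outliers were left out, spots of one probe were averaged as log2 of the processed signal, and each array's 75th percentile was subtracted. Probes were named through the RefSeq gene table supplied for the rat, 21109 by accession, 6684 by current symbol and 424 by synonym, and 17381 kept the name in the file. Of several probes of a gene, the one with the highest mean over all arrays stood for it. Features were tested where that probe was well above background on at least 5 of the 12 arrays, which left 14742 features, 10090 of them with a gene symbol. In 31 called features another probe of the gene also passed this filter, and in 0 of them did such a probe go the other way. The size differed between probes for some of the named genes and was close for others.

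The knockout was compared with the wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are differences of mean log2 signal, knockout minus wild type. Vdac1 was also tested per probe with an exact two-sided permutation test over all 792 splits of the 12 arrays into 7 and 5. Before the list tests, 14 missing values took the mean of their group's other arrays. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 28 lists with at least 5 members tested, and again with an estimated correlation and with fry. Of these 28 lists 14 passed with the preset correlation, 0 with an estimated correlation (6 at unadjusted p under 0.05) and 15 with fry, which tests a list against no change and not against other genes. The lists, the tests above, the rule for naming genes and the alternatives were fixed before the data were examined, with exceptions. These are 5 alternatives, and further tests of explanations, that the closing sections name as chosen after the data or results were seen. The genes named are Vdac1, Vdac2 and Vdac3, the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap and whose probe was well above background on every array of the brighter group, with names of predicted or unnamed features left out, and up to 4 called members per list, or the member with the smallest p where none passed. Other genes given as examples of a list were chosen after their values were seen. The values of some genes are not reported here.

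The lists held subunits of complex I, of complexes II and III, of complex IV and of ATP synthase, the TCA cycle and pyruvate oxidation, glycolysis, partners of the VDAC family, mitochondrial import, dynamics and mitophagy, biogenesis, ribosomal proteins of mitochondria and cytosol, mitochondrial chaperones and proteases, fatty acid oxidation, antioxidant and NRF2 targets, the integrated stress response, the unfolded protein response of the endoplasmic reticulum, apoptosis regulators, p53 targets, hypoxia-inducible genes, cholesterol synthesis, the cell cycle, interferon-stimulated genes, inflammatory cytokines, and markers of dopaminergic, neuronal, progenitor, astrocyte, oligodendrocyte, microglial, fibroblast and endothelial cells.

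The fit was tested on simulated data for the comparison of 7 knockout with 5 wild-type arrays, over 14740 features with independent noise of the real spread and 200 changed features. Of the simulated features changed by 0.5 on the log2 scale 5.97% were recovered, of those changed by 1, 50.8%, and of those changed by 2, 89.4%. Of 103 calls in the simulation, 6 were of unchanged features. Of 28 simulated lists, the list moved by 0.5, glycolysis, was called with camera, and so was 1 other list. Some of the other lists share members with glycolysis, so whether that call was false is not known. With independent noise the simulation does not test camera under correlation between genes.

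Alternatives tried were quantile normalization, centring on the median of probes well above background on all arrays, no scaling, normexp background correction (offset 50), the deposited value table, no filter and a strict filter on dim probes, the mean over a gene's probes, slide as a block, the sample number as a block, each slide alone, eBayes with trend and robust, array weights, leaving out each array, stricter thresholds, and the other list tests.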

Results

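The data comprise 12 arrays of N27 cells, a rat line derived from midbrain neurons, with 7 cultures of the Vdac1 knockout and 5 of the wild type. The comparison the design names asks which transcripts differ when VDAC1, a channel for metabolites across the outer mitochondrial membrane, is lost. Pearson correlations between arrays lay between 0.935 and 0.992. The arrays did not separate first by genotype. On the first principal component, which held 37.4% of the variance, the 5 arrays whose sample numbers in the labels are 1 to 4 (KO 1 to KO 4 and WT 3) lay between 32.0 and 44.2, and the 7 arrays numbered 5 to 8 between -45.2 and -14.8.

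**Figure D1:**
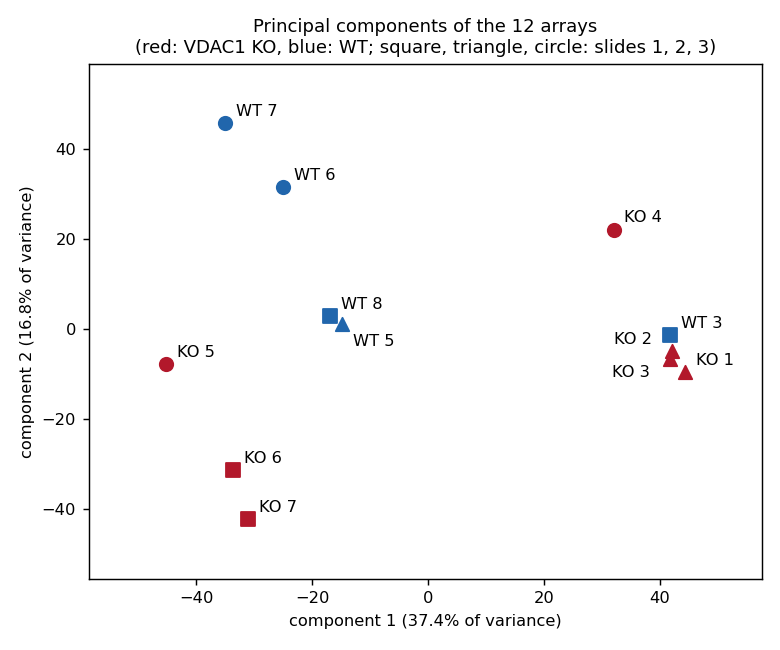
Each point is 1 array, placed by its scores on the first and second principal components of the 14742 features, which hold 37.4% and 16.8% of the variance (red, knockout; blue, wild type; square, triangle and circle, slides 1, 2 and 3). KO 1 to KO 4 and WT 3 lie on the right, at 32.0 or above, and the other 7 arrays on the left.

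Vdac1 signal was lower in every knockout array than in every wild-type array, on each of the 3 probes for the gene. The brightest probe, at base 1724 of the transcript, averaged 1.98 ± 0.65 (SD, n = 7) in the knockout and 3.21 ± 0.23 (SD, n = 5) in the wild type on the log2 scale relative to the array's 75th percentile, 2.34-fold lower in the knockout (exact two-sided permutation p = 0.00505). The probe at base 880 differed by -1.22 (exact permutation p = 0.00126, the smallest that 792 splits can give) and the probe at base 630 by -1.15 (exact permutation p = 0.00631). With each probe fitted on its own, limma's adjusted p was 0.0562, 0.0423 and 0.0897 in that order. At the brightest probe the signal was 2.54, 2.45, 2.68 and 2.26 in KO 1 to KO 4 and 1.21, 1.53 and 1.20 in KO 5 to KO 7. It was 3.61 in WT 3, 3.14 in WT 5, 3.07 in WT 6, 3.16 in WT 7 and 3.07 in WT 8. The transcript remained measurable, with all 3 probes well above background on all 12 arrays. The file coordinates place the probes on chromosome 10 at 37823174 to 37823233, 37822333 to 37822392 and 37819583 to 37819641, in the order given. The headers name build rn4, which was not checked against a genome here, and where the edit lies relative to the probes is not given in the sources used here, so the signal may not show whether the protein was lost.

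In the fit over all features Vdac1 missed the threshold (log2 fold change -1.23, SE 0.28, limma adjusted p = 0.0560). The Vdac1 log2 fold change passed with slide as a block (-1.38, adjusted p = 0.0224), and within slides 1, 2 and 3 it was -1.97, -0.58 and -1.38. With the sample numbers, 1 to 4 against 5 to 8, as a block it was -1.58 (adjusted p = 0.000527), and over its 30 alternatives the adjusted p ran from 0.000527 to 1.00. Vdac2 and Vdac3, the other channel isoforms, gave no called difference, at -0.037 (SE 0.23, adjusted p = 0.961) and 0.21 (SE 0.20, adjusted p = 0.659).

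**Figure D2:**
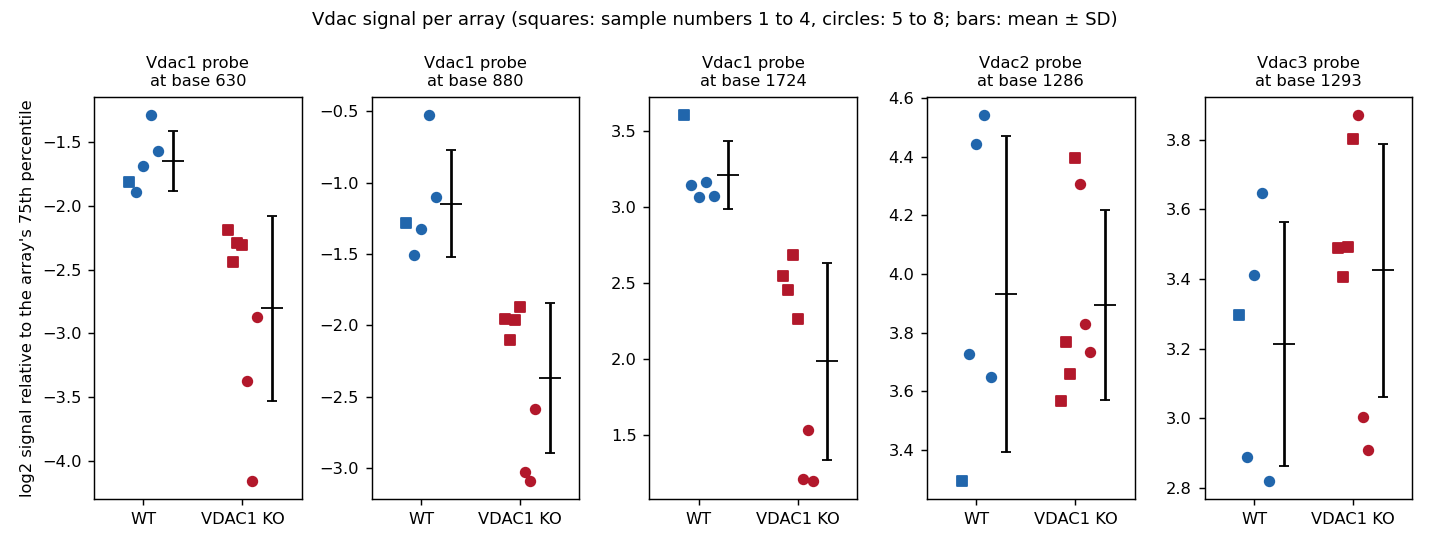
Log2 signal relative to the array's 75th percentile for the 3 Vdac1 probes and for the Vdac2 and Vdac3 probes, 1 point per array (squares, sample numbers 1 to 4; circles, 5 to 8), with mean ± SD of 5 wild-type and 7 knockout arrays beside them. At the Vdac1 probe at base 1724 all knockout points lie at or below 2.68 and all wild-type points at or above 3.07.

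Across the 14742 features, 103 rose and 58 fell in the knockout (limma, adjusted p under 0.05). With normexp background correction limma called 16 higher and 9 lower, with an index of RNA quality as a covariate 13 and 9, and without the filter on dim probes 0 and 0 (1981 at unadjusted p under 0.05). Plaat3, a phospholipase and acyltransferase of lipid metabolism, rose by 2.41 (SE 0.41, adjusted p = 0.0230). Its probe was well above background on 2 of the 5 wild-type arrays, so the size rests in part on signal at background, and with normexp the Plaat3 log2 fold change was 0.63 (adjusted p = 0.278). The secretory granule protein gene Ptprn rose by 1.37 and Pparg, a nuclear receptor of lipid metabolism, by 1.30, and their probes were well above background on 4 and 3 wild-type arrays. Bnip3, a mitophagy receptor of the outer mitochondrial membrane, rose by 1.24 (SE 0.17, adjusted p = 0.00696), from 0.0050 ± 0.24 (SD, n = 5) to 1.24 ± 0.28 (SD, n = 7). Ltb, which encodes a cytokine of the tumour necrosis factor family, rose by 1.22, and Septin5, well above background on 3 wild-type arrays, by 1.19. Tpi1, the glycolytic triosephosphate isomerase, rose by 1.08 (SE 0.13, adjusted p = 0.00424), Tpi1l1, named as like it, by 1.06 and the Gapdh pseudogene Gapdh-ps1 by 1.00. Whether the probes for these copies read the parent genes' transcripts is uncertain. The galectin gene Lgals5 rose by 0.94 and the alpha-globin gene Hba-a1 by 0.90. Another Lgals5 probe differed by 0.53.

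Hapln1, which encodes a link protein of hyaluronan in the extracellular matrix, fell by 2.10 (SE 0.33, adjusted p = 0.0197). Its probe was well above background on 3 of the 7 knockout arrays, and with normexp the Hapln1 log2 fold change was -0.65 (adjusted p = 0.427). Npy, the neuropeptide Y gene, fell by 1.64 (SE 0.18, adjusted p = 0.00348) and was well above background on 5 of the 7, and with normexp the Npy log2 fold change was -0.69 (adjusted p = 0.211). Nupr1, a stress-induced regulator of transcription, fell by 1.49 (SE 0.21, adjusted p = 0.0109), from 2.77 ± 0.51 (SD, n = 5) to 1.28 ± 0.26 (SD, n = 7). The gene for the microtubule-associated protein Map1b fell by 1.39, the integrin gene Itgb5 by 1.20, and Pycr1, which makes proline in mitochondria, by 1.15. Scara3 fell by 1.09, Lrrcc1 by 1.02, Fam13a by 0.98, Tbl1xr1 by 0.96, Tp53i11 by 0.90 and Psph, an enzyme of serine synthesis, by 0.87. Another Tbl1xr1 probe differed by -0.59. Fam13a was well above background on 5 and Tp53i11 on 6 of the 7 knockout arrays. Of the rises and falls named here and above, those of Bnip3, Tpi1, Tpi1l1, Nupr1, Map1b and Pycr1 passed with normexp too and the others did not. The offset of 50 used with normexp shrinks log2 differences most at dim probes. A call lost there does not show that a dim gene is unchanged.

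**Figure D3:**
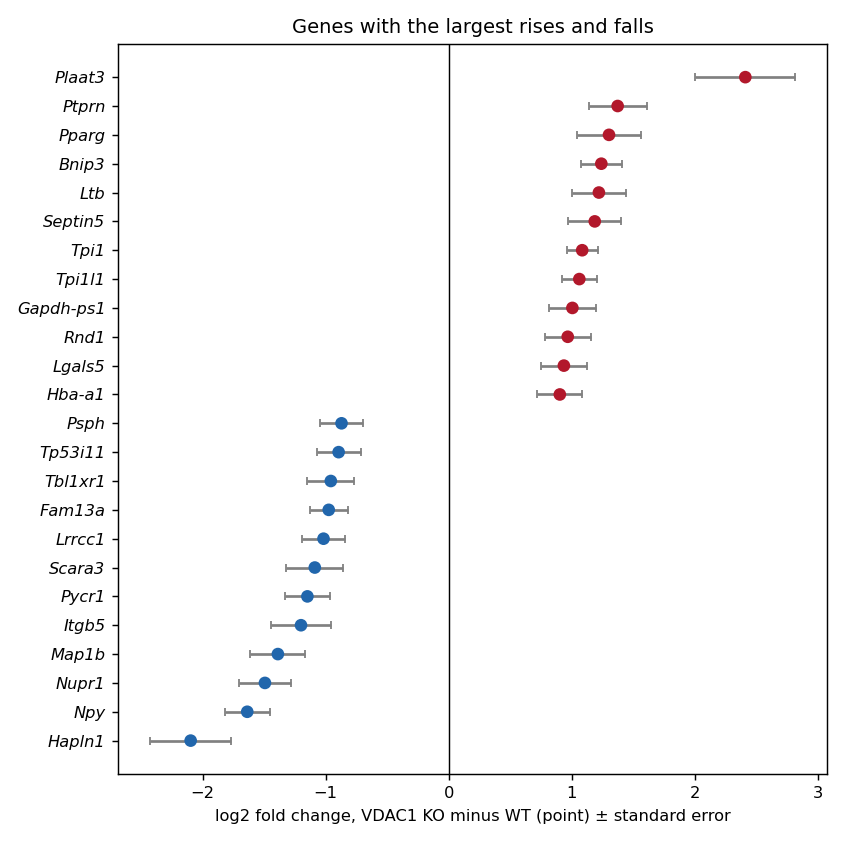
Log2 fold change, knockout minus wild type, with its standard error, for the 12 named genes with the highest fitted values among the rises (red) and the 12 with the lowest among the falls (blue), from 7 knockout and 5 wild-type arrays, some of them at background on part of the arrays. Values run from -2.10 for Hapln1 to 2.41 for Plaat3.

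Of the rises 44 had a gene symbol and 59 did not, and of the falls 46 had a symbol and 12 did not. In 139 of the 161 calls the groups did not overlap, and over all features 2.73% showed no overlap, where chance gives 0.253%. Each of the 161 calls had the same sign within slides 1, 2 and 3, which is part of what made it a call, since the same arrays were used. With slide as a block 253 features rose and 151 fell. Within slide 2, where the lone wild-type array differs from the knockout arrays in sample number too, 1062 rose and 924 fell, and within slides 1 and 3 limma called 0 (1754 and 783 at unadjusted p under 0.05). The counts moved by over 1.5 times in at least 1 direction without any 1 of the 12 arrays, from 9 to 383 rises and from 3 to 268 falls, with the highest counts without WT 3. Of the called genes named, Bnip3, Tpi1, Tpi1l1, Npy and Nupr1 passed without any 1 of the 12 arrays, and each of the others lost its call without at least 1. With the sample numbers as a block, a split placed after the arrays were seen to separate this way, 446 rose and 303 fell, among them all 161 calls. In numbers 5 to 8 alone limma called 96 of the 161, and in numbers 1 to 4 alone, where WT 3 is the lone wild-type array, 3.

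Glycolytic genes were higher in the knockout as a group, with a median log2 fold change of 0.46 (camera adjusted p = 8.4e-06; adjusted p = 0.0555 with an estimated correlation). Of 20 members measured, 2 rose, 0 fell and 18 did not pass over all features (limma; 12 higher and 1 lower at unadjusted p under 0.05), and adjusted over the list alone 11 were higher and 1 lower. Limma called 4 higher and 0 lower with the sample numbers as a block, and 6 and 1 in numbers 5 to 8 alone. Tpi1 rose by 1.08 and the aldolase gene Aldoa by 0.85 (SE 0.15, adjusted p = 0.0240). Slc16a3, a lactate exporter, differed by 0.81 (adjusted p = 0.0567), Gapdh by 0.74 (adjusted p = 0.136) and Pfkfb3, a regulator of glycolytic flux, by -0.46 (adjusted p = 0.164). The glycolysis median log2 fold change was 0.48 with slide as a block and 0.40, 0.59 and 0.50 within slides 1, 2 and 3. It was 0.65 in numbers 5 to 8 alone and 0.11 in numbers 1 to 4 alone, where the list did not pass (adjusted p = 0.637, the highest over its alternatives, of which the lowest was 4.9e-11).

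Among genes of mitochondrial respiration limma called 0 of the 35 complex I subunits (3 higher at unadjusted p under 0.05), 0 of 14 subunits of complexes II and III (2 higher), 0 of 14 of complex IV (4 higher, 1 lower) and 0 of 17 of ATP synthase (2 higher). In the simulation 5.97% of changes of 0.5 were recovered, so changes of that size are not excluded. As lists, complex I had a median log2 fold change of 0.15 (camera adjusted p = 0.0210) and complexes II and III of 0.20 (adjusted p = 0.0159), both with an adjusted p = 0.241 with an estimated correlation. Complex IV (0.21, adjusted p = 0.122) and ATP synthase (0.13, adjusted p = 0.0540) missed the threshold. With the sample numbers as a block complex I lost its call (0.13, camera adjusted p = 0.127), and complexes II and III kept theirs (0.17, adjusted p = 0.0345). Adjusted over the list alone, Uqcrc2 (0.38) and Uqcrh (0.42) of complex III were higher and Cox6a2, the muscle-type isoform of a complex IV subunit, was lower (-1.84, SE 0.51, adjusted p over all features = 0.0998). With the sample numbers as a block Uqcrh (0.46, adjusted p = 0.0383) and Cox6a2 (-1.14, adjusted p = 0.0111) passed over all features, as they did in numbers 5 to 8 alone (0.58 and -1.32). Ndufc2 of complex I differed by 0.39 (adjusted p = 0.129) and Atp5f1b of ATP synthase by 0.35 (adjusted p = 0.198). The TCA cycle and pyruvate oxidation had a median of 0.21 (adjusted p = 0.0105; adjusted p = 0.0555 with an estimated correlation) with 0 of 25 members called (3 higher at unadjusted p under 0.05). Pdk1, which restrains pyruvate oxidation, differed by 0.79 (adjusted p = 0.145), and its 3 other passing probes by 0.23 to 0.97. With slide as a block the complex I subunits median log2 fold change was 0.18, that of complex II and III subunits 0.19 and that of the TCA cycle and pyruvate oxidation 0.22. Within slides 1, 2 and 3 these were 0.13, 0.28 and 0.15, then 0.24, 0.15 and 0.27, then 0.24, 0.22 and 0.15. Under quantile normalization complex I (0.089, adjusted p = 0.692) and complexes II and III (0.12, adjusted p = 0.404) no longer passed. Without WT 5 (0.13) or WT 8 (0.14) complex I did not pass, nor did complexes II and III without WT 7 (0.15).

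**Figure D4:**
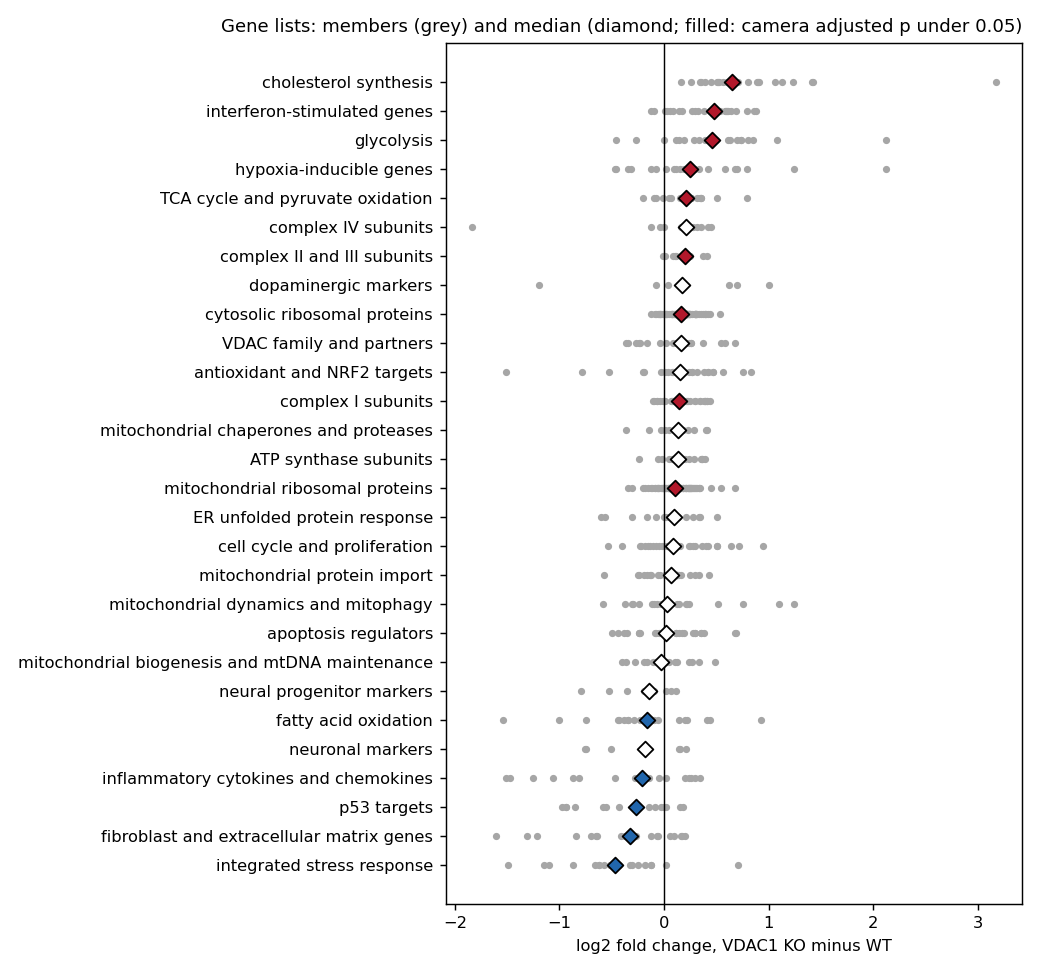
Log2 fold change, knockout minus wild type, of each member (grey points) of the 28 lists tested, with the list's median as a diamond that is filled where camera's adjusted p is under 0.05 (red, above 0; blue, below 0). The medians run from -0.47 for the integrated stress response to 0.65 for cholesterol synthesis.

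Genes of the integrated stress response, which includes amino acid synthesis under the transcription factor Atf4, were lower as a group, with a median of -0.47 (camera adjusted p = 1.5e-09; adjusted p = 0.0555 with an estimated correlation). Of 21 members, 0 rose, 4 fell and 17 did not pass over all features (limma; 1 higher and 11 lower at unadjusted p under 0.05), and adjusted over the list alone 1 was higher and 10 lower. The members called lower were 7 with the sample numbers as a block and 8 in numbers 5 to 8 alone. The 4 were Nupr1 (-1.49), Pycr1 (-1.15), Psph (-0.87) and Aldh18a1, a step of proline synthesis (-0.62, adjusted p = 0.0408). Trib3 differed by -1.10 (adjusted p = 0.0578), and Gdf15, which goes against the list, by 0.71 (adjusted p = 0.152). The integrated stress response median log2 fold change was -0.52 with slide as a block and -0.49, -0.39 and -0.62 within slides 1, 2 and 3. It was -0.71 in numbers 5 to 8 alone and -0.20 in numbers 1 to 4 alone, where the list did not pass.

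Genes of cholesterol synthesis were higher as a group, with a median of 0.65 over 22 members, all of them with a positive value (camera adjusted p = 2.1e-09; adjusted p = 0.219 with an estimated correlation). Over all features 1 rose, Insig1, a regulator of the pathway (1.42, SE 0.29, adjusted p = 0.0408), and 0 fell (limma; 13 higher and 0 lower at unadjusted p under 0.05), and adjusted over the list alone 10 were higher. Limma called 6 higher and 0 lower with the sample numbers as a block, and 4 and 0 in numbers 5 to 8 alone. The Insig1 signal was 1.90 in WT 3, within the knockout's range, and between -0.048 and 0.10 in the other 4 wild-type arrays. The cholesterol synthesis median log2 fold change was 0.60 with slide as a block, 0.052 (adjusted p = 0.803) within slide 1, which holds WT 3, and 1.21 and 0.86 within slides 2 and 3. It was 0.41 with the sample numbers as a block, 0.52 in numbers 5 to 8 alone and 0.013 in numbers 1 to 4 alone, where the list did not pass.

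Interferon-stimulated genes had a median of 0.48 over 27 members (camera adjusted p = 1.0e-05; adjusted p = 0.0744 with an estimated correlation). Of these 1 rose, 0 fell and 26 did not pass over all features (limma; 13 higher and 0 lower at unadjusted p under 0.05), and 2 were higher adjusted over the list alone. Those called higher were 3 with the sample numbers as a block and 2 in numbers 5 to 8 alone. The called member was Oasl, an antiviral gene of the oligoadenylate synthetase family (0.88, SE 0.16, adjusted p = 0.0307). Isg15, the ubiquitin-like modifier, differed by 0.59 (adjusted p = 0.205). The interferon-stimulated genes median log2 fold change was 0.37 with slide as a block and 0.22 (adjusted p = 0.0566), 0.26 and 0.40 within slides 1, 2 and 3, and 0.31 in numbers 5 to 8 alone.

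Hypoxia-inducible genes had a median of 0.25 (camera adjusted p = 0.0345; adjusted p = 0.149 with an estimated correlation). Of 23 members 1 rose, Bnip3, and 0 fell (limma; 8 higher and 2 lower at unadjusted p under 0.05), with 4 higher and 1 lower adjusted over the list alone. Members such as Slc2a1, Ldha, Hk2 and Aldoc are in the glycolysis list too, so the results of both lists are not independent. The 17 members outside that list, taken apart after the whole list's result was seen, had a median of 0.19. Their unadjusted camera p was 0.0472, and 0.0926 with an estimated correlation. The p53 targets had a median of -0.27 (adjusted p = 0.000839; adjusted p = 0.241 with an estimated correlation). Of 18 members the growth arrest gene Gadd45a fell by 0.86 and 0 rose (limma; 5 lower and 0 higher at unadjusted p under 0.05), and 3 were lower adjusted over the list alone, among them Cdkn1a, the cell cycle inhibitor p21 (-0.98, adjusted p over all features = 0.120). The p53 targets median log2 fold change was -0.20 with slide as a block and 0.19, -0.62 and -0.43 within slides 1, 2 and 3. Fatty acid oxidation had a median of -0.17 (adjusted p = 0.0359; adjusted p = 0.243 with an estimated correlation), where Cpt1b, a carnitine palmitoyltransferase, fell by 0.74, and adjusted over the list alone 1 was higher and 1 lower. Another Cpt1b probe differed by -0.39. Inflammatory cytokines and chemokines had a median of -0.21 (adjusted p = 0.0244; adjusted p = 0.329 with an estimated correlation) with 0 of 18 called by limma (5 lower at unadjusted p under 0.05). With slide as a block and then within slides 1, 2 and 3, the hypoxia-inducible genes median log2 fold change was 0.25, 0.35, 0.25 and 0.29, the fatty acid oxidation median log2 fold change -0.13 (adjusted p = 0.0564), 0.26, -0.37 and -0.22, and the inflammatory cytokines and chemokines median log2 fold change -0.26, -0.083, -0.32 and -0.37. With the sample numbers as a block limma called 3 hypoxia-inducible genes higher, 2 p53 targets lower, 2 genes of fatty acid oxidation higher and 2 lower, and 1 inflammatory gene lower. With that block the adjusted p was 0.0567 for p53 targets, 0.127 for inflammatory cytokines and for complex I, and 0.360 for fatty acid oxidation. With no scaling between arrays, which moved the median of all features to 0.28, the fatty acid oxidation median log2 fold change was 0.077 and the inflammatory cytokines and chemokines median log2 fold change 0.036, both below that shift. In numbers 1 to 4 alone, where 4 knockout arrays are set against WT 3 only, the p53 targets median log2 fold change was 0.11, the hypoxia-inducible genes median log2 fold change 0.0073, and the inflammatory cytokines and chemokines median log2 fold change 0.39. Without KO 5 (0.19), KO 6 (0.23), WT 6 (0.19) or WT 8 (0.22) the hypoxia-inducible genes median log2 fold change did not pass, nor did that of fatty acid oxidation without KO 1 (-0.13), KO 3 (-0.14), KO 4 (-0.16), WT 5 (-0.15) or WT 7 (-0.11), or that of inflammatory cytokines and chemokines without WT 6 (-0.13) or WT 8 (-0.16). Without WT 3 the fatty acid oxidation median log2 fold change was -0.28, the inflammatory cytokines and chemokines median log2 fold change -0.32 and the p53 targets median log2 fold change -0.50, and without WT 5 that of p53 targets was -0.16.

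Ribosomal protein genes were tested in 2 lists. Those of the cytosol had a median of 0.16 (camera adjusted p = 0.000169; adjusted p = 0.418 with an estimated correlation), with 0 of 76 called by limma (8 higher at unadjusted p under 0.05), a direction that flipped to -0.018 under quantile normalization and to -0.017 in the deposited value table. With the sample numbers as a block the list did not pass (0.071, adjusted p = 0.248), and without WT 3 the cytosolic ribosomal proteins median log2 fold change was 0.26. Mitochondrial ribosomal proteins had a median of 0.11 (adjusted p = 0.0314; adjusted p = 0.344 with an estimated correlation), with 0 of 69 called (9 higher and 1 lower at unadjusted p under 0.05). The mitochondrial ribosomal proteins median log2 fold change was 0.18 with the sample numbers as a block and did not pass without KO 4 (0.11), KO 5 (0.080), WT 3 (0.11), WT 5 (0.079) or WT 8 (0.097). Within slides 1, 2 and 3 it was 0.21, 0.20 and 0.11, and the cytosolic ribosomal proteins median log2 fold change was -0.038, 0.35 and 0.21. Rpl32 differed by 0.54 (adjusted p = 0.0885) and Mrpl10 by 0.54 (adjusted p = 0.136).

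Markers of cell types were measured in part. Of the 24 dopaminergic markers on the array 7 were tested and limma called 0 over all features (2 higher and 1 lower at unadjusted p under 0.05). Adjusted over the list alone, Gch1, which makes the cofactor of tyrosine hydroxylase, was higher (0.70, adjusted p over all features = 0.0522), as was Maoa, a monoamine oxidase (1.00), and Nr4a2, a transcription factor of dopaminergic neurons, was lower (-1.19). The Nr4a2 probe was well above background on 1 knockout and 4 wild-type arrays and the Maoa probe on 7 and 4. Th, the tyrosine hydroxylase gene, differed by 0.17 (adjusted p = 0.703). Of 22 neuronal markers 6 were tested and 0 called over all features, and Ncam1, a cell adhesion molecule, was lower adjusted over the list alone (-0.76, adjusted p over all features = 0.0869). Of 13 progenitor markers 8 were tested and 0 called (2 lower at unadjusted p under 0.05), with Vim at -0.52 (adjusted p = 0.294). As lists, dopaminergic (median 0.17, adjusted p = 0.339), neuronal (-0.18, adjusted p = 0.372) and neural progenitor markers (-0.14, adjusted p = 0.107) did not pass. The neuronal markers median log2 fold change had no settled sign, at 0.061 with no scaling, 0.12 with the sample numbers as a block, 0.37 in numbers 5 to 8 alone, -0.46 without WT 6 and -0.067 without KO 4. The neural progenitor markers median log2 fold change was 0.099 with no scaling, -0.25 with that block, -0.28 without WT 3 and -0.091 without KO 2, and in numbers 5 to 8 alone it passed (-0.25, adjusted p = 0.0266). Gch1 (0.66, adjusted p = 0.0361), Ncam1 (-0.93, adjusted p = 0.0121) and the endothelial Flt1 (-1.05, adjusted p = 0.0307) passed over all features with that block. Limma with the block also called 1 neural progenitor marker and 1 fibroblast and extracellular matrix gene lower. Fibroblast and extracellular matrix genes had a median of -0.32 (camera adjusted p = 0.00616; adjusted p = 0.0555 with an estimated correlation) with 0 of 18 called (5 lower at unadjusted p under 0.05) and 3 lower adjusted over the list alone, among them the proteoglycan gene Bgn (-0.64, adjusted p over all features = 0.103). The fibroblast and extracellular matrix genes median log2 fold change was -0.42 with slide as a block and -0.42, 0.095 and -0.32 within slides 1, 2 and 3, and -0.16 in numbers 1 to 4 alone, where the list did not pass. It was -0.15 without KO 5, -0.17 without KO 6 and -0.21 without WT 3. Too few astrocyte (3), oligodendrocyte (4), microglial (3) and endothelial (3) markers were measured for a list test, and limma called 0 of them (1 at unadjusted p under 0.05, the endothelial Flt1, at -0.90 with adjusted p = 0.0998, while another Flt1 probe differed by -0.0016).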

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

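The tests of slide, genotype and swapped labels for the split by sample number, of gene copies, of the number sets for glycolysis, and of splits within the number sets were chosen after the results were seen.

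In 7 of 113 sets of values (1 gene in 1 group) a single array lay far from the others of its group, where chance gives about 1 in 20. The total is close to that rate. The sets share the same arrays, and most of those flagged lay in WT 3, so the rate does not show that chance accounts for them. In WT 3 these were Insig1, at 1.895 against at most 0.1029 in the other wild-type arrays, Plk1, at 2.801 against at most 1.595, Vdac1, at 3.607 against at most 3.163, Timm8a1, at 0.2735 against at least 0.7989, and Ccl7, at -0.5204 against at least 2.003. The 2 others were Gch1 in KO 5, at -1.832 against at least -1.401, and Gapdh-ps1 in WT 7, at 0.9103 against at least 1.602. WT 3 is the only wild-type array among the sample numbers 1 to 4.

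Sample numbers 1 to 4 stood apart from numbers 5 to 8. The split calls 3736 features by limma in a fit without genotype. Genotype calls 161 in a fit without the sets and 749 with the set as a block. Because the split was placed where the arrays were seen to separate, a large count follows from that choice and adds no independent support. The 3736 may also include differences of genotype, since KO 1 to KO 4 and only WT 3 make up numbers 1 to 4. Slide or scan is argued against, since each of the 3 slides held arrays of both sets. That the sets lay apart on the first principal component on each slide follows from how they were chosen. Array brightness is argued against too, since 0.9521 of the features called between the sets stayed called with brightness as a covariate. Genotype is argued against by 4 arrays on the other genotype's side, and swapped labels by the Vdac1 signal, which lay on the other genotype's side of the midpoint in 0 of those 4; a first form of this test, over all arrays, found 1, KO 3, at 2.68 against a midpoint of 2.60 and still below every wild-type array. A difference between culture rounds, passages or clones was not tested, because the sources used here name none, and it stays open.

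Of the risen features without a gene symbol, 22 of 59, a share of 0.3729, are described as copies of glycolytic enzyme genes or share at least 20 bases of probe sequence with a probe for one, against 1.48% of such features that did not pass. The share lies between the bounds set for and against copies as the account of these rises, so it does not decide. For the 22, a rise of their own cannot be told apart from signal of the parent genes, because the probes may read both, and the other 37 are not accounted for. Without the 22, 81 rises remain. No biological explanation was tested.

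The median of the glycolytic genes, 0.4569, was 0.4739 with an index of RNA quality, the signal of downstream over upstream probes of 529 transcripts, 0.4423 with array brightness and 0.5442 with the number sets, each with a camera p under the threshold, which argues against each as the whole cause. Within the sets it was 0.65 in numbers 5 to 8 and 0.11, not passing, in numbers 1 to 4, which hold 1 wild-type array, and the difference between the sets was not tested. The calls over all features fell to 13 higher and 9 lower with the RNA index, which itself averaged -0.021 in the knockout and 0.027 in the wild type (exact permutation p = 0.182). What stays open is the knockout itself, which the design names, a general response of hypoxia-inducible genes, and any difference between cultures that moves with genotype.

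Of 100 splits drawn from the 792 splits of the 12 arrays into 7 and 5, 2 called as many features as the real one, itself included, with 161 for the real split and 229 for the highest other drawn. The split by sample number, which is among the 792 but was not drawn, calls 3736, and these splits do not keep the number sets together. Splits within the number sets, fitted with the set as a block, were therefore counted too: 1 of 100 drawn from 175, the real one, called as many, with 749 features against 126 for the highest other, and 94 of the other 99 called 0. By the splits within the sets, chance is argued against for the count of calls made with the set as a block, and not for any single call. The splits assume that cultures within a set are exchangeable, which is not given in the sources used here. The sets themselves were placed after the data were seen. A cause that moves with genotype within the sets is not excluded by these splits.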

How the results depend on the processing

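The 5 alternatives on number sets and on features with a symbol were chosen after the data were seen. Vdac1 kept its direction in all 30 alternatives run for it (-1.97 to -0.58) and glycolysis in all 34 run for the lists (0.11 to 0.70), while the counts of calls moved widely. Over these alternatives the adjusted p ran from 0.000527 to 1.00 for the Vdac1 log2 fold change, 4.9e-11 to 0.637 for glycolysis, 7.6e-05 to 0.817 for complex I, 0.000122 to 1.00 for complexes II and III, 5.2e-21 to 0.916 for cholesterol synthesis and 4.0e-13 to 0.5676 for the integrated stress response. On the Vdac1 probe the groups did not overlap. The Vdac1 direction therefore could not turn where arrays were left out or taken by slide or number set. For glycolysis, the other list tests use the median of the main fit. Those settings add no support for either direction. Signal over background limits dim probes, and the number of arrays and the separation by sample number limit the rest. Calls gained and lost below cover Vdac1 and all 28 lists, with the log2 change or list median in parentheses. A list's direction is that of camera's test, so that the median can have the other sign where a call was lost. Except where a setting tests fewer features or fewer arrays by its construction, the cause was not tested.

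Under quantile normalization, 56 features rose and 48 fell by limma, 9 lists passed, calls were gained for Vdac1 (-1.33), calls were lost for complex I (0.089), complex II and III (0.12), mitochondrial ribosome (0.078), fatty acid oxidation (-0.19), and the direction turned for cytosolic ribosome (-0.018). With no scaling between arrays, 4 features rose and 0 fell by limma (255 at unadjusted p under 0.05), and calls were lost for complex I (0.39), complex II and III (0.45), TCA cycle (0.45), mitochondrial ribosome (0.35). With normexp background correction, 16 features rose and 9 fell by limma, calls were gained for complex IV (0.21), ATP synthase (0.15), mitochondrial chaperones (0.13), antioxidant targets (0.12), and calls were lost for fatty acid oxidation (-0.12). In the deposited value table, 54 features rose and 50 fell by limma, 8 lists passed, calls were gained for Vdac1 (-1.35), calls were lost for complex I (0.068), complex II and III (0.10), mitochondrial ribosome (0.059), fatty acid oxidation (-0.19), hypoxia (0.17), and the direction turned for cytosolic ribosome (-0.017). With no filter on dim probes, 0 features rose and 0 fell by limma (1981 at unadjusted p under 0.05), calls were gained for complex IV (0.21), ATP synthase (0.13), antioxidant targets (0.15), and calls were lost for fatty acid oxidation (-0.17). With only probes above background on all arrays, 182 features rose and 109 fell by limma, calls were gained for Vdac1 (-1.23), and calls were lost for hypoxia (0.19). With the mean over a gene's probes, calls were gained for Vdac1 (-1.20), ATP synthase (0.16). With slide as a block, 253 features rose and 151 fell by limma, calls were gained for Vdac1 (-1.38), complex IV (0.23), and calls were lost for fatty acid oxidation (-0.13). In slide 1 alone, 0 features rose and 0 fell by limma (1754 at unadjusted p under 0.05), 3 lists passed, calls were lost for complex I (0.13), complex II and III (0.24), TCA cycle (0.24), mitochondrial ribosome (0.21), hypoxia (0.35), cholesterol synthesis (0.052), interferon (0.22), cytokines (-0.083), and the direction turned for cytosolic ribosome (-0.038), fatty acid oxidation (0.26), p53 targets (0.19). In slide 2 alone, 1062 features rose and 924 fell by limma, calls were gained for ATP synthase (0.28), unfolded protein response (0.45), cell cycle (0.27), and calls were lost for complex II and III (0.15), TCA cycle (0.22), hypoxia (0.25), extracellular matrix (0.095). In slide 3 alone, 0 features rose and 0 fell by limma (783 at unadjusted p under 0.05), 8 lists passed, and calls were lost for complex I (0.15), complex II and III (0.27), TCA cycle (0.15), mitochondrial ribosome (0.11), fatty acid oxidation (-0.22), hypoxia (0.29). With trend and robust in eBayes, 205 features rose and 100 fell by limma, and calls were gained for Vdac1 (-1.23), ATP synthase (0.13). With array weights, 2709 features rose and 2287 fell by limma, calls were gained for Vdac1 (-0.72), ATP synthase (0.20), unfolded protein response (0.41), cell cycle (0.21), and calls were lost for complex II and III (0.15), hypoxia (0.28), the fibroblast and extracellular matrix genes median log2 fold change (-0.0050). At adjusted p under 0.01, 8 features rose and 2 fell by limma. At a fold change of at least 2, 34 features rose and 22 fell by limma. With an estimated correlation, 0 lists passed, so that each of the 14 lost its call, among them complex I (0.15), complex II and III (0.20), TCA cycle (0.21), glycolysis (0.46). With fry, calls were gained for complex IV (0.21), ATP synthase (0.13), mitochondrial chaperones (0.13), antioxidant targets (0.15), neural progenitor markers (-0.14), and calls were lost for cytosolic ribosome (0.16), fatty acid oxidation (-0.17), p53 targets (-0.27), cytokines (-0.21). The share of rises among the calls was 53.8% under quantile normalization and 51.9% in the deposited table, against 64.0%. With no scaling the median of all features was 0.28. The weights were highest on WT 8 (3.98), KO 3 (3.39), KO 2 (2.51), WT 5 (2.37) and KO 1 (2.08), and between 0.30 and 0.81 on the others. The weighted fit therefore sets mostly KO 1 to KO 3 against WT 5 and WT 8, which differ in number set too. Its calls cannot be read as differences of genotype alone.

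With the number set as a block, 446 features rose and 303 fell by limma, 9 lists passed, calls were gained for Vdac1 (-1.58), and calls were lost for complex I (0.13), cytosolic ribosome (0.071), fatty acid oxidation (0.0011), p53 targets (-0.069), cytokines (-0.14). In numbers 5 to 8 alone, 332 features rose and 345 fell by limma, calls were gained for Vdac1 (-1.80), neural progenitor markers (-0.25), calls were lost for TCA cycle (0.28), fatty acid oxidation (-0.072), and the direction turned for unfolded protein response (-0.10). In numbers 1 to 4 alone, 42 features rose and 5 fell by limma, 2 lists passed, calls were lost for complex II and III (0.050), TCA cycle (0.18), glycolysis (0.11), mitochondrial ribosome (0.062), fatty acid oxidation (-0.13), integrated stress response (-0.20), hypoxia (0.0073), cholesterol synthesis (0.013), extracellular matrix (-0.16), and the direction turned for complex I (-0.030), cytosolic ribosome (-0.082), p53 targets (0.11), cytokines (0.39). Among features with a symbol, 40 features rose and 38 fell by limma, calls were gained for ATP synthase (0.13), and calls were lost for fatty acid oxidation (-0.17). With number set and slide as blocks, 925 features rose and 702 fell by limma, 9 lists passed, and calls were lost for complex I (0.14), cytosolic ribosome (0.075), fatty acid oxidation (-0.0028), p53 targets (-0.074), cytokines (-0.16). Numbers 1 to 4 hold 1 wild-type array, assumed to vary like the others.

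With the sample number as a replicate block, limma called 0 rises and 0 falls (1534 at unadjusted p under 0.05), 5 lists passed, and lost were the calls of complex I (0.14), complex II and III (0.20), TCA cycle (0.24), mitochondrial ribosome (0.14), cytosolic ribosome (0.059), fatty acid oxidation (-0.027), p53 targets (-0.12), hypoxia (0.29), cytokines (-0.19). No sign was found that the numbers pair the samples, though with 4 shared numbers a pairing cannot be excluded. Deviations from the group means of same-numbered samples correlated at 0.462, -0.109, 0.0731 and 0.0499 for numbers 3, 5, 6 and 7. KO 3 and WT 3 also share the number set, which may account for the 0.462. Of 8 samples 2 correlated best with their own number, about what chance gives. With few numbers shared, this block also leaves few residual degrees of freedom.

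Leaving out 1 array gave these rises and falls: 20 and 12 without KO 1, 9 and 6 without KO 2, 16 and 12 without KO 3, 57 and 26 without KO 4, 72 and 36 without KO 5, 46 and 25 without KO 6, 34 and 19 without KO 7, 383 and 268 without WT 3, 10 and 4 without WT 5, 12 and 3 without WT 6, 20 and 14 without WT 7, 11 and 3 without WT 8. The lists that passed ranged from 10 to 15, and the log2 values were ATP synthase 0.12 to 0.19, TCA cycle 0.18 to 0.24, Vdac1 -1.34 to -1.10, complex I 0.13 to 0.18, complex II and III 0.15 to 0.21, complex IV 0.14 to 0.26, glycolysis 0.43 to 0.60. Complex I was lost without WT 5 (0.13) and WT 8 (0.14), complex II and III without WT 7 (0.15). ATP synthase passed without KO 7 (0.17), WT 3 (0.19) and WT 6 (0.17), and complex IV without WT 7 (0.26).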

Other observations

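The tests of hypoxia-inducible genes below were chosen after the result of the whole hypoxia list was seen.

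Among lists that did not pass, antioxidant and NRF2 targets moved both ways. Limma called 0 of 28 over all features (5 higher and 3 lower at unadjusted p under 0.05), and adjusted over the list alone 3 were higher and 2 lower (list median 0.15, camera adjusted p = 0.115, fry adjusted p = 0.0392). The 2 lower were Slc7a11, the cystine transporter (-1.52, adjusted p over all features = 0.0561), and the exporter gene Abcc1 (-0.79), both of which passed over all features with the sample numbers as a block (-1.24, adjusted p = 0.0453, and -0.88, adjusted p = 0.0259), and the 3 higher were the peroxiredoxin genes Prdx1 (0.38) and Prdx3 (0.42) and the ferritin gene Fth1 (0.42). Among 22 VDAC family members and partners (median 0.16, adjusted p = 0.510), limma called 0 (3 higher and 1 lower at unadjusted p under 0.05), and Ppif, cyclophilin D of the mitochondrial matrix, was higher adjusted over the list alone (0.55, adjusted p over all features = 0.0853). Ppif passed over all features with the sample numbers as a block (0.61, adjusted p = 0.0329) and in numbers 5 to 8 alone (0.76, adjusted p = 0.0414). In numbers 5 to 8 alone Hk2 was also called higher (0.88, limma adjusted p = 0.0156) and Mcub lower (-1.17, adjusted p = 0.00437). Among 23 genes of mitochondrial protein import (median 0.072, adjusted p = 0.957), 0 were called (2 higher and 1 lower at unadjusted p under 0.05), and Timm8a1 was lower adjusted over the list alone (-0.58, adjusted p over all features = 0.0759) and passed with that block (-0.45, adjusted p = 0.0466). Among 22 genes of mitochondrial dynamics and mitophagy (median 0.028, adjusted p = 0.995) Bnip3 alone passed.

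Other lists gave no call by limma or camera in the main fit, and some of them passed under alternatives given above. These were mitochondrial chaperones and proteases (median 0.13, adjusted p = 0.336; Phb1 at 0.41), mitochondrial biogenesis (-0.024, adjusted p = 0.883; Endog at 0.34), the unfolded protein response of the endoplasmic reticulum (0.10, adjusted p = 0.895; Herpud1 at -0.60), the cell cycle (0.087, adjusted p = 0.468; Plk1 at 0.95) and apoptosis regulators (0.020, adjusted p = 0.964; Casp9 at 0.69). The Casp9 probe was well above background on 4 knockout and 2 wild-type arrays. For apoptosis regulators the median and the mean (0.052) were positive and camera's direction was down. At unadjusted p under 0.05 the counts, higher and lower, were 2 and 1, 1 and 0, 1 and 1, 3 and 1, and 3 and 4 in that order. Of the markers of other cell types, Cnp differed by 0.45, Gja1 by 0.38 and Cd68 by -0.43, with 0 of these called. With the sample numbers as a block Plk1 passed (0.54, adjusted p = 0.0280), and in numbers 5 to 8 alone Herpud1 did (-1.16, adjusted p = 0.0169). By fry, the mitochondrial chaperones and proteases passed (adjusted p = 0.0391), and the other 4 lists did not.

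A hypothesis is that the rise of glycolytic genes may be part of a general response of hypoxia-inducible genes. The 17 hypoxia-inducible genes outside the glycolysis list had a median of 0.1898, against 0.4569 for glycolysis. Their camera p was 0.0472, just under the threshold set for the test, and 0.0926 with an estimated correlation, and the test was written after the result of the whole list was seen. Of the 17, 12 had a positive value and limma called 1, Bnip3, while Vegfa (-0.47), Egln3 (-0.34) and Adm (-0.31), which also respond to hypoxia, were negative and not called. Over the whole hypoxia list limma called 3 higher and 0 lower with the sample numbers as a block. In numbers 5 to 8 alone it called 6 higher and 2 lower. Some of these calls are members of the glycolysis list too. Slc2a1 is among the higher in both fits, and in numbers 5 to 8 Hk2 and Aldoc are among the higher and Pfkfb3 among the lower. The counts over the whole list therefore cannot test the hypothesis. The hypothesis stays open, with Bnip3 as its clearest member.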
